A study of Mus musculus with 4 samples.

How the data were processed

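The series held 4 mouse samples, made of a gene expression library and a T-cell receptor library for each of 2 treatments. The treatments were all-trans retinoic acid (ATRA, the active acid form of vitamin A) at 10 mg/kg and its control, given every other day. Per the labels, tumors were dissected with the brain around them, dissociated with Accutase, and sorted for CD45, a surface protein of immune cells. Libraries were made with a 10x Genomics 5-prime kit, which tags each captured RNA molecule with a cell barcode and a unique molecular identifier (UMI). The 2 gene expression libraries were not analysed here, so no cell type or state was assigned from expression. The 2 receptor libraries, 1 per treatment, gave all values below.

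Each receptor library came as 1 table of assembled contigs, which are receptor transcripts rebuilt from the reads of 1 barcode. The submitters' processing notes name bcl2fastq 2.20.0, Cell Ranger 3.1.0 and mouse genome build GRCm38. Per the file headers, the deposited values are counts of UMIs and counts of reads for each contig, with no normalization, beside the V, D, J and C segment names, the CDR3 as amino acids and nucleotides, and a clonotype number. The CDR3 is the hypervariable loop that spans the V-J junction. All contigs in both tables were marked as belonging to a cell and as high confidence, so 0 contigs were removed on those columns. No contig had a D segment name. None of the 81 control and 185 ATRA contigs with a TRBJ2 segment had a C segment name, against 28 of 34 and 86 of 95 contigs with a TRBJ1 segment, so C segments were not used. The steps that set the deposited cell calls and clonotype numbers are not described further in the sources used here.

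A chain was counted when its contig was marked productive and belonged to the alpha (TRA) or beta (TRB) locus. A cell was a barcode with at least 1 such chain, and a paired cell had at least 1 of each. Cells with more than 1 productive TRB or more than 2 productive TRA were counted as having extra chains and were kept; no doublet caller was run. Clonotypes were those of the deposited numbers, which treat a cell with a missing TRA as another clonotype than a cell with the same TRB and a TRA. An expanded clonotype had 2 or more cells. Shares carry exact (Clopper-Pearson) 95% binomial intervals, numbers of cells exact Poisson intervals, and ratios of shares exact conditional intervals. Where a count was 0, a floor of 3 counts set the upper limit of the share and stood in for the count in the ratio. Such a ratio leaves out the error of the other count, which the exact limits hold. All intervals and floors cover counting error only. They leave out differences between mice, and cells of 1 clone are not independent.

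Distinct clonotypes were compared at equal numbers of cells by the exact hypergeometric expectation. The repeat probability was the chance that a pair of cells drawn without replacement shared a clonotype. For comparison of pairing across depths, each cell was thinned to 4 receptor UMIs, the lower of the 2 library medians, and cells below that were left out. Segment use was the share of cells with a productive chain of the locus. The text names the 5 clonotypes with most cells in each library, any clonotype in both libraries, and the 3 most used TRAV, TRAJ, TRBV and TRBJ segments of each library. Ties between clonotypes were broken by the deposited number and ties between segments by name, and segments tied for the third place are given too. It also names segments with at least 10 cells over both libraries whose shares differed at least 2-fold, up to 12. Families of TRAV and TRBV segments, TRBJ clusters and TRAJ segments numbered 25 or lower were preset lists. Preset receptors were those of invariant natural killer T cells (TRAV11 or TRAV11D with TRAJ18) and mucosal-associated invariant T cells (TRAV1 with TRAJ33), any TRGV or TRDV chain and any immunoglobulin chain. These rules and the main alternatives were fixed before the data were examined. Receptors outside them are said to have been chosen after their values were seen.

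With 1 library per treatment no test between treatments was possible, and none was run. The number of mice behind each library is not given in the sources used here. Segment names matched gene symbols of the RefSeq annotation of GRCm38.p6 for 122 of 123 segments, from which coordinates were taken. The name TRBV12-2+TRBV13-2, under which the deposited tables report 1 fused segment, had no match. The ratio interval was tested on simulated data drawn from the TRBV counts. Over 200 simulations of 21 segments it covered the true ratio in 98.6% of the ratios scored. Only simulated segments with at least 10 cells and at least 1 control cell were scored, with cells drawn independently. Ratios of rarer segments, ratios with no control cell, and cells of 1 clone were therefore not tested. Alternatives were a minimum of 2 or 3 UMIs per chain, paired cells alone, cells without extra chains, clonotypes by TRB or by amino acids, a threshold of 3 cells, other counting units, thinning, drawing down, and leaving out the largest clonotype. Clonotypes by amino acids were counted in paired cells only. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.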

Results

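The study addressed retinoic acid signaling and immune escape in gliomas with mutant IDH. Mice of the C57BL6 strain received 50000 glioma neurosphere cells at 6 weeks of age and were then treated with ATRA or control. T-cell receptors were sequenced in 1 library of sorted immune cells from control tumors and 1 from ATRA-treated tumors, so no value below has a replicate. The control library held 159 contigs in 74 cells, of which 108 were productive chains with 382 UMIs. The ATRA library held 496 contigs in 160 cells, of which 308 were productive chains with 1841 UMIs. No barcode occurred in both libraries (0 shared).

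The first comparison asked how many T cells with a receptor each library held and how complete the receptors were. T cells with a receptor numbered 74 in the control library (exact Poisson 95% interval 58.1 to 92.9) and 160 in the ATRA library (136 to 187), 2.16 times as many. These numbers also depend on how many cells were loaded, which the receptor tables do not hold. Both chains of the alpha-beta receptor were found in 30 of 74 control cells, 40.5% (29.3 to 52.6), and in 121 of 160 ATRA cells, 75.6% (68.2 to 82.1). The missing chain was mostly the alpha chain. A TRB without a TRA was found in 40 control cells, 54.1% (42.1 to 65.7), and 27 ATRA cells, 16.9% (11.4 to 23.6), while a TRA alone was found in 4 and 12 cells.

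Receptor depth moved with these shares. The median was 4 receptor UMIs per cell in the control library (quartiles 3 and 6) and 9 in the ATRA library (quartiles 6 and 14). TRA chains had a median of 2 UMIs (quartiles 1 and 3) against 3 (2 and 5), and TRB chains 3 (2 and 5) against 6 (4 and 9). Over all contigs the control library had 9798 reads per UMI and the ATRA library 4465. After thinning to 4 UMIs, 39.7% of 52 control cells (27.0 to 54.9) and 59.2% of 152 ATRA cells (51.0 to 67.1) were paired, and 22 and 8 shallower cells were left out. The same cells before thinning gave 44.2% and 76.3%. Extra chains were found in 4 control cells, 5.41% (1.49 to 13.3), and 13 ATRA cells, 8.12% (4.40 to 13.5).

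**Figure D1:**
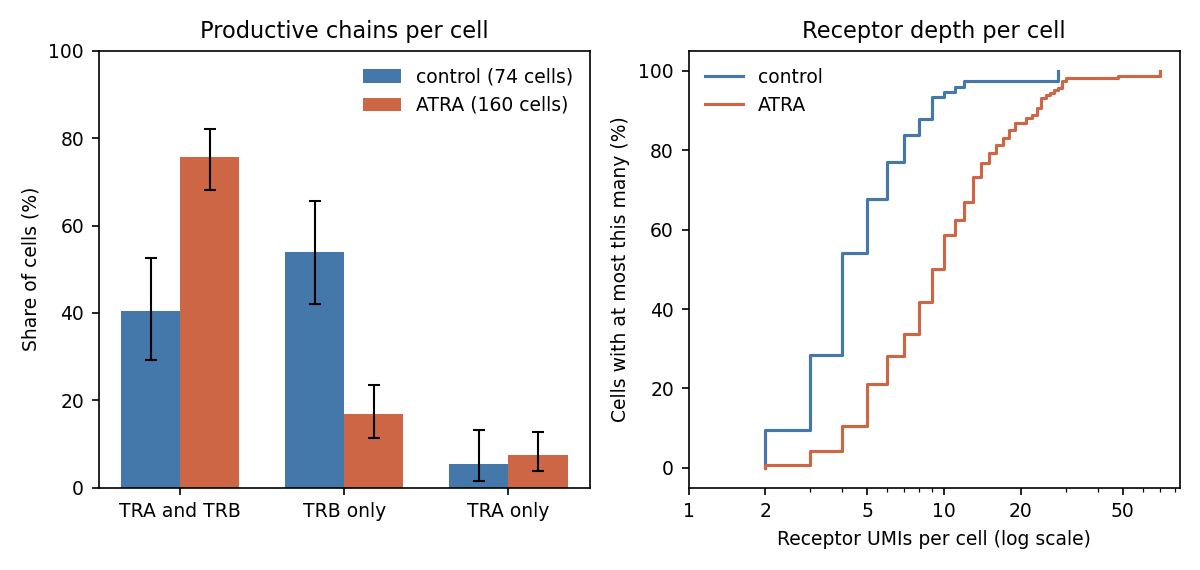
Left, share of cells (%) with both chains, a TRB alone or a TRA alone in the control (74 cells) and ATRA (160 cells) libraries, with exact 95% binomial intervals as error bars. Right, cumulative share of cells (%) against receptor UMIs per cell on a log scale; the ATRA curve lies to the right, with a median of 9 UMIs against 4.

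The next comparison was of clonal expansion, that is, how often several cells carried 1 receptor. Most clonotypes were single cells in both libraries, 58 of 65 in control and 109 of 128 in ATRA. Expanded clonotypes held 16 of 74 control cells, 21.6% (12.9 to 32.7), and 51 of 160 ATRA cells, 31.9% (24.7 to 39.7). Drawn down to 74 cells, the ATRA library had a mean of 20.6% of cells in expanded clonotypes (SD of the draws 4.79), so the higher ATRA share was not detectable at equal numbers of cells. It held 65.0 distinct clonotypes (SD of the draws 2.32) at that size, against 65 in control. The largest clonotype held 3 control cells, 4.05% (0.844 to 11.4), and 7 ATRA cells, 4.38% (1.78 to 8.81). The repeat probability was 0.407% in control and 0.487% in ATRA.

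These values depend on the clonotype definition, because 1 TRB was often divided over several deposited clonotypes. This held for 5 TRB sequences in 19 control cells and 14 TRB sequences in 48 ATRA cells. With clonotypes defined by TRB alone, expanded clonotypes held 28.6% of 70 control cells (18.4 to 40.6) and 45.9% of 148 ATRA cells (37.7 to 54.3). The repeat probabilities then changed order, to 1.28% and 0.938%, and the largest clonotype held 8.57% of control cells and 5.41% of ATRA cells. Drawn down to 70 cells, the ATRA library had 31.97% of cells in expanded TRB clonotypes (SD of the draws 5.77).

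The clonotypes with most cells had different CDR3s in the 2 libraries, while TRBV29 with TRBJ2-1 and TRAV9-2, and TRBV5, were used among them in both. In ATRA the first paired TRAV6-6 and TRAJ39 (CDR3 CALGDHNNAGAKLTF) with TRBV5 and TRBJ2-4 (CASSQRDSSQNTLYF) in 7 cells. The second paired TRAV21-DV12 and TRAJ53 (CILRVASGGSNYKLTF) with TRBV26 and TRBJ2-1 (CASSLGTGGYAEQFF) in 6 cells, 3.75% (1.39 to 7.98). The third paired TRAV3D-3 and TRAJ40 with TRBV19 and TRBJ1-6 in 4 cells, and the other two used TRAV9-2 with TRBV29 and TRAV4-4-DV10 with TRBV29, in 3 cells each. In control, a TRBV29 and TRBJ2-1 chain (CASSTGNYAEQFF) occurred alone in 3 cells and with TRAV9-2 and TRAJ31 (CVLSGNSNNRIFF) in 3 more. The remaining 3 named control clonotypes had 2 cells each, as did 2 others that are not named, and were taken by their deposited number. They were TRAV12D-3 with TRAJ12 and no TRB, TRAV7-3 and TRAJ27 with TRBV5 and TRBJ2-2, and TRBV12-2+TRBV13-2 with TRBJ1-1 and no TRA.

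The comparison of receptors between the libraries asked which clonotypes occurred in both. Of 29 control and 107 ATRA pairs of TRA and TRB, 2 were identical in V, J and nucleotides. The first joined TRAV21-DV12 and TRAJ53 to TRBV26 and TRBJ2-1, with the CDR3s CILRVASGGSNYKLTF and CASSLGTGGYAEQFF, in 1 control and 1 ATRA cell. The second joined TRAV12-2 and TRAJ26 (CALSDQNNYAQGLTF) to TRBV20 and TRBJ1-1 (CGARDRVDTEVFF), in 1 control and 2 ATRA cells. By single chains, 3 TRB and 2 TRA chains identical in V, J and nucleotides were shared, and 4 TRB and 2 TRA CDR3 amino acid sequences. The shared pairs rest on few molecules, and 1 of the 2 was left when chains needed 2 UMIs and 0 when they needed 3.

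The first of these receptors, singled out after its values were seen, recurred with other nucleotide sequences. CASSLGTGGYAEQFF was carried by 9 of 70 control cells with a TRB, 12.9% (6.05 to 23.0), and by 14 of 148 ATRA cells, 9.46% (5.27 to 15.4). With any residue at position 5 of the CDR3, the group held 9 control cells, 12.9%, and 20 ATRA cells, 13.5% (8.45 to 20.1). The lower ATRA share was thus not kept in this wider group. It includes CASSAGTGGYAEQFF, in 5 ATRA and 0 control cells. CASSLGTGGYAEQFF itself was encoded by 9 nucleotide sequences, or 10 combinations of V segment and nucleotides, 6 in control and 5 in ATRA, with 1 in both. TRBV26 carried it in 7 control and 12 ATRA cells, and TRBV14 in 2 and 2. The most frequent sequence was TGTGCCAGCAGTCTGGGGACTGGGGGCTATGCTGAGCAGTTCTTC with TRBV26, in 8 ATRA cells and 0 control cells. In control it was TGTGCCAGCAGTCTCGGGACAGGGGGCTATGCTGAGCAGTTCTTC with TRBV26, in 3 cells.

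The alpha chain beside it was nearly always the same. Among cells with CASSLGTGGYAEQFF and a TRA, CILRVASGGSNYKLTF was found in 3 of 4 control cells and 11 of 12 ATRA cells, 91.7% (61.5 to 99.8). Among paired cells without this TRB, or a form of it with any residue at position 5 of the CDR3, it was found in 0 of 26 control cells and 1 of 105 ATRA cells, 0.952% (0.0241 to 5.19). In GRCm38, TRBV26 lies on chromosome 6 at 41227525 to 41227913, TRBV14 at 41135167 to 41135616 and TRBJ2-1 at 41542754 to 41542803. TRAV21-DV12 lies on chromosome 14 at 53876016 to 53876752 and TRAJ53 at 54162644 to 54162709.

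**Figure D2:**
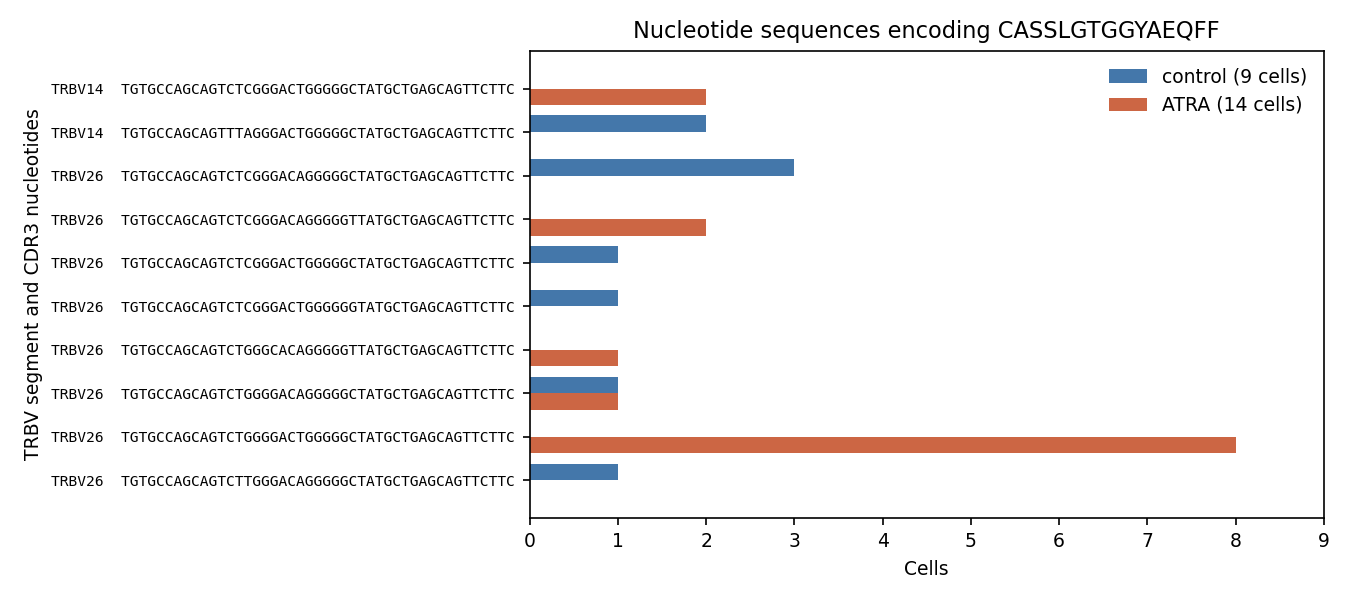
Cells (horizontal axis) that carried each combination of TRBV segment and CDR3 nucleotide sequence encoding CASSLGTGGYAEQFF, in the control (9 cells) and ATRA (14 cells) libraries. A single combination occurred in both libraries, with 1 cell in each, and 8 ATRA cells shared the most frequent one.

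Segment use was compared to see whether the libraries drew on different V and J segments. Among TRAV families, TRAV6 differed most in percentage points, with 31 of 133 ATRA cells, 23.3% (16.4 to 31.4), against 0 of 34 control cells, which allows up to 8.82%. With the floor of 3 counts set for control the ratio was 2.64, and its exact lower limit was 2.02. That limit makes no allowance for picking the largest difference among 14 TRAV families. The 31 ATRA cells used 10 TRAV6 segments in 23 clonotypes, the largest of 7 cells. TRAV14 family segments were used by 14 ATRA cells, 10.5% (5.88 to 17.0), and 1 control cell, 2.94% (0.0744 to 15.3), a ratio of 3.58 (0.545 to 151). In the beta chain, the TRBV13 family without the fused segment was used by 18.2% of ATRA cells (12.4 to 25.4) and 8.57% of control cells (3.21 to 17.7), a ratio of 2.13 (0.861 to 6.30). That ratio rests on leaving out the fused segment, whose name holds TRBV13-2, since with it the family was used by 27.1% of control (17.2 to 39.1) and 27.0% of ATRA cells (20.1 to 34.9), an alternative chosen after the values were seen. With at least 2 UMIs per chain both families had 0 control cells, and the exact lower limits of the ratio were 1.26 for TRAV6 and 0.663 for TRAV14. With at least 3 they were 0.615 and 0.366.

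Of 123 segments found, 57 occurred in both libraries, and 26 had at least 10 cells. Among these, 7 differed at least 2-fold, and the counting interval of each of the 7 ratios included 1. Higher shares in ATRA were found for TRBJ2-4, with 8.78% of cells (4.76 to 14.6) against 1.43% (0.0362 to 7.70) and a ratio of 6.15 (0.924 to 261), and for TRBV14, with 8.78% against 2.86% and a ratio of 3.07 (0.696 to 28.1). TRAV14D-1 and TRAJ40 each had 9 ATRA cells and 1 control cell, a ratio of 2.30 (0.319 to 101). Lower shares in ATRA were found for TRBJ2-2, with a ratio of 0.405 (0.113 to 1.41), TRAJ26, with 0.447 (0.114 to 2.08), and TRBV12-2+TRBV13-2, with 8.78% (4.76 to 14.6) against 18.6% (10.3 to 29.7) and a ratio of 0.473 (0.202 to 1.11). All 4 control cells with TRAJ26, and 4 of its 7 ATRA cells, carried 1 CDR3, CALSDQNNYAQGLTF. The fused segment, with 13 cells in each library, was the most used TRBV name in control. Under 5 alternatives (at least 2 or 3 UMIs per chain, paired cells, no cells with extra chains, distinct clonotypes), TRBV14 alone of the 7 stayed past the size rule each time. TRBJ2-4, with 7 of its 13 ATRA cells in 1 clonotype, had 0 of 48 control and 11 of 131 ATRA cells left at 3 UMIs. With the floor set for control its ratio was then 1.34, with an exact lower limit of 0.920. Over clonotypes its ratio was 3.68, from 1 control and 7 ATRA clonotypes, too few for the rule. TRAJ40, with 4 of its 9 ATRA cells in 1 clonotype, had ratios of 1.80 at 2 UMIs, 0.791 at 3 UMIs, 1.24 in paired cells and 1.11 over clonotypes. TRAV14D-1 had no control cell left at 2 or 3 UMIs, and ratios of 1.24 in paired cells and 1.66 over clonotypes.

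Among the most used segments, TRBJ2-1 led the TRBJ segments in both, with 30.0% of control cells (19.6 to 42.1) and 30.4% of ATRA cells (23.1 to 38.5), followed by TRBJ1-1 with 14.3% and 15.5% and TRBJ2-7 with 14.3% and 12.8%. TRBV26 was used by 15.7% and 11.5%, TRBV29 by 14.3% and 10.8%, TRBV5 by 11.4% and 10.8%, and TRBV13-1 by 7.14% and 11.5%. TRAV21-DV12 was used by 14.7% of control cells (4.95 to 31.1) and 12.8% of ATRA cells (7.63 to 19.7), TRAJ53 by 8.82% and 11.3%, TRAJ39 by 5.88% and 7.52%, and TRAV12-2 by 11.8% and 6.02%. All 3 control and 15 ATRA cells with TRAJ53 carried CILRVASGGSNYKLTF. They made up most of the 5 control and 17 ATRA cells with TRAV21-DV12. The 10 ATRA cells with TRAJ39 were 2 clonotypes, and over distinct clonotypes the TRAJ39 shares were 7.14% of control and 1.98% of ATRA. All 4 control cells with TRAV12-2 carried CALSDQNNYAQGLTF. The remaining frequent TRA segments rested on few cells. TRAV7-3 was found in 5 control cells, 14.7% (4.95 to 31.1), and 0 of 133 ATRA cells, which allows up to 2.26%. The exact upper limit of its ratio was 0.279, and it was 0.266 to 0.420 under the 5 alternatives. These limits make no allowance for naming TRAV7-3 by its high control share among 54 TRAV segments, and the alternatives reuse the same cells. The copy of TRAV7-3, TRAV7D-3, was found in 0 control and 2 ATRA cells. The TRAV7 family as a whole was used by 17.6% of control cells (6.76 to 34.5) and 12.8% of ATRA cells (7.63 to 19.7). TRAJ34 was found in 0 of 34 control cells and 17 ATRA cells, 12.8% (7.63 to 19.7), a ratio of 1.45 with the floor set for control. The exact lower limit of that ratio was 1.05, and it was below 1 under each of the 5 alternatives. TRAV6-6 was found in 0 control cells and 9 ATRA cells, TRAJ12 in 3 and 1, TRAJ27 in 3 and 2, TRAJ31 in 3 and 6, and TRAV9-2 in 4 and 5.

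**Figure D3:**
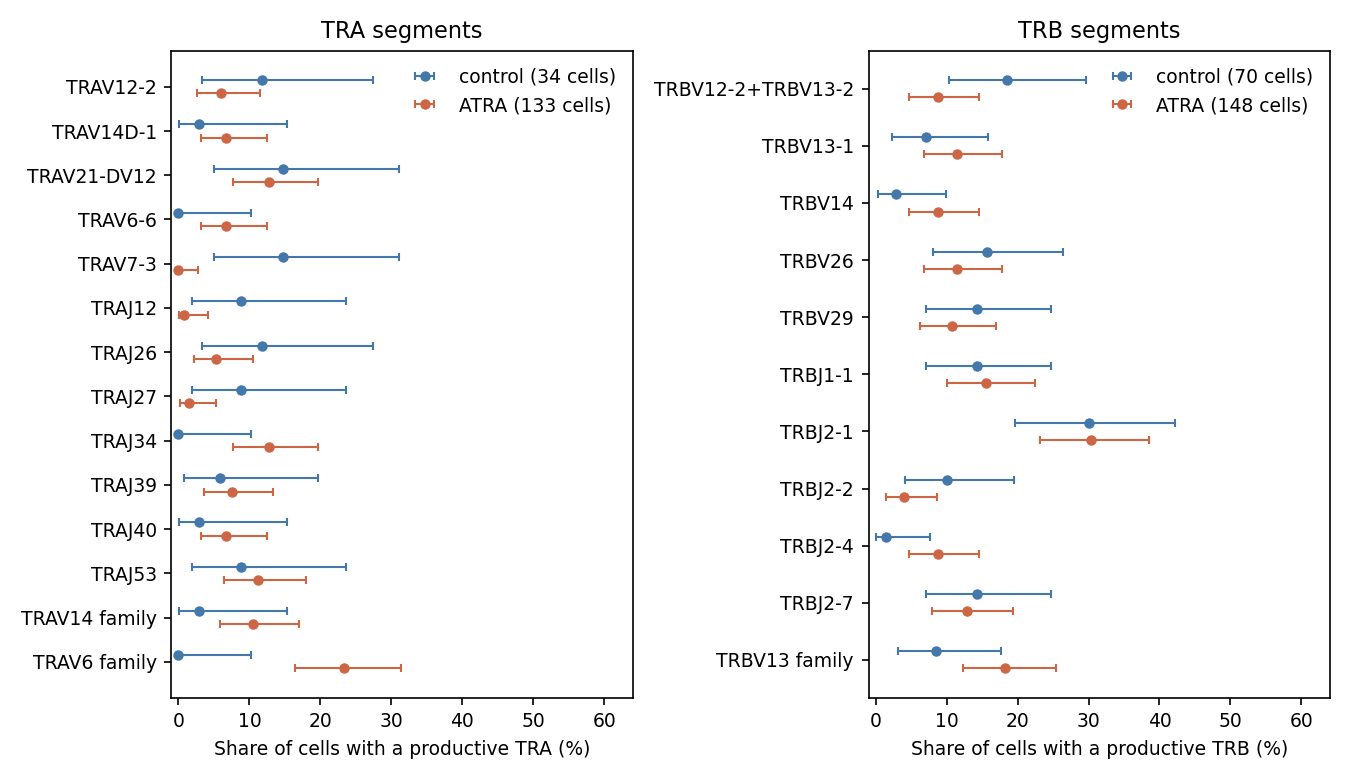
Share of cells (%) with a productive TRA (left, 34 control and 133 ATRA cells) or TRB (right, 70 control and 148 ATRA cells) that used each named segment or family; points are shares and bars exact 95% binomial intervals. The intervals of the 2 libraries part for the TRAV6 family (0 against 23.3%) and TRAV7-3 (14.7% against 0) and overlap for every other segment or family drawn.

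Receptors of unconventional T cells were also looked for. The receptor of invariant natural killer T cells, which recognise lipids on CD1d, was found in 0 of 34 control cells and 0 of 133 ATRA cells with a TRA, which allows up to 8.82% and 2.26%. The receptor of mucosal-associated invariant T cells, which recognise vitamin B metabolites on MR1, was also found in 0 cells of each library, with the same limits. TRAJ18 occurred with other V segments in 1 control and 3 ATRA cells. Contigs with a TRGV or TRDV segment were found in 1 control and 2 ATRA cells, and none was productive. Every cell in the tables had a productive TRA or TRB, so this sets no limit on gamma-delta T cells. No immunoglobulin contig was found; the libraries were made for T-cell receptors, so this says nothing on B cells.

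CDR3 lengths and J positions were compared last. TRA CDR3s averaged 13.7 amino acids in control (SD 1.72, n = 28 chains of distinct clonotypes) and 14.0 in ATRA (SD 1.35, n = 113). TRB CDR3s averaged 14.0 in both (SD 1.29, n = 66, and SD 1.31, n = 131), and the median was 14 for both loci and libraries. TRBJ2 segments were used by 71.4% of control cells with a TRB (59.4 to 81.6) and 64.2% of ATRA cells (55.9 to 71.9). TRAJ segments numbered 25 or lower, at the end of the locus next to the constant region, were used by 23.5% (10.7 to 41.2) and 24.8% (17.7 to 33.0). The differences in TRBJ2 and TRAJ shares were within the counting intervals and not detectable at this depth.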

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

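The test on recurring TRB sequences and the thinning were written down before their results were seen. No test in this part was chosen after, but the rule used to read the first was.

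Nonproductive contigs, which the comparisons above do not use, were more frequent per cell in the ATRA library, with 188 contigs in 160 cells or 1.175 per cell (exact Poisson 95% interval 1.01 to 1.36), than in the control library, with 51 in 74 cells or 0.689 (0.513 to 0.906). Of these, 93 ATRA and 28 control contigs had no V segment name. The ATRA cells were also deeper, with a median of 9 productive receptor UMIs per cell against 4. Productive chains held 1841 of 2520 contig UMIs in ATRA and 382 of 539 in control. Per UMI the nonproductive part was thus similar in the 2 libraries.

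Fewer control cells had both chains, 40.5% against 75.6%. A lower number of receptor UMIs per cell may account for part of this, since thinning to 4 UMIs brought the ATRA share from 76.3% to 59.2% (51.0 to 67.1). The thinned control share was 39.7%, below that interval, while its own upper bound of 54.9% reached into it, so depth as the whole cause cannot be told apart from a remaining difference at this number of cells. If barcodes with a TRB alone held free RNA of other cells, their TRB sequences would recur in other barcodes more often; 8 of 40 such control cells had a recurring TRB, 20.0% (9.05 to 35.6), against 13 of 30 paired control cells, 43.3% (25.5 to 62.6). The direction was the reverse of the one named for free RNA. The upper bound of 35.6% lay below the paired share of 43.3%, so the bound set beforehand against free RNA was met. That bound left out the error of the paired share. By a rule chosen after the result, which uses both intervals, free RNA stays open because they overlap. The treatment itself, which is confounded with the library, stays open as well.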

How the results depend on the processing

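Merging duplicated TRAV copies, adding the fused segment to TRBV13 and recounting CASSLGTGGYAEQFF were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because each treatment had 1 library. Of 282 recomputed values, 248 stayed within the counting interval of the reported value, or within 1.5 times for counts. This count says little on robustness, since the recounts reuse the same cells and 126 values were segment ratios, many with wide intervals. For instance, the TRAV14D-1 ratio of 0.6 at 2 UMIs counted as within its interval. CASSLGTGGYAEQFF stayed within its counting interval in all 10 recounts. Recounts over cells gave 10.6% to 13.8% of control and 9.63% to 10.7% of ATRA cells. Over distinct clonotypes the shares were 12.9% and 6.78%. A minimum of 2 UMIs per chain left 18.9% of control and 61.0% of ATRA cells paired and 1 shared pair. A minimum of 3 left 55 control cells, 9.09% and 47.0% paired, 12.7% of control cells in expanded clonotypes, 0 shared pairs and 3 segments past the size rule, 1 of them among the 7 reported (TRBV14), and turned the TRAJ40 ratio to 0.791; fewer chains remain by construction. With the fused segment the TRBV13 family ratio was 0.996. Thinning gave 59.2% paired ATRA cells. Without cells with extra chains, 1 shared pair was left. Over distinct clonotypes, 4 segments were past the size rule, TRBV14 and 3 others. Repeat probabilities were 1.38% (control) and 0.826% (ATRA) in paired cells, 1.28% and 0.938% by TRB alone, and 1.38% and 1.38% by amino acids, with control slightly higher (1.379 against 1.377). Expanded clonotypes held 45.9% of ATRA cells with a TRB by TRB alone. Counting by amino acids used paired cells only, where expanded clonotypes held 43.0% of paired ATRA cells and the largest held 9.09%. With the deposited clonotypes, paired ATRA cells gave 38.8% and 5.79%. The control values were 30.0% and 10.0% either way. Expanded clonotypes held 8.11% of control and 14.4% of ATRA cells at 3 or more cells, by construction, and 20.6% of ATRA cells when drawn down. Where no construction is named, the cause was not tested. Of 71 comparisons recomputed for both libraries, 16 changed order, among them the largest clonotype, repeat probability and distinct clonotypes in paired cells, by TRB and by amino acids. Paired and expanded shares were higher in ATRA under every alternative that kept the cell numbers unequal. TRA values rest on 34 control cells.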

Other observations

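The drawing down of cells and the test on divided clones were planned, the first with its bound set after related values were seen. The tests on carry-over, errors and pairing, and the receptors named here, were chosen after the results were seen.

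Other groups of similar receptors occurred besides the one described. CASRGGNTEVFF was carried by 7 ATRA cells and 0 of 70 control cells, which allows up to 4.29%, and was made by 4 nucleotide sequences with TRBV13-1 or TRBV13-3. All 6 of these cells with a TRA used TRAJ34, in 4 nucleotide sequences with TRAV14D-1 (4 cells) or TRAV9N-4 (2 cells), against 9 of 115 other paired ATRA cells, 7.83% (3.64 to 14.3). Their TRA CDR3s were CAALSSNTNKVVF, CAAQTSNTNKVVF, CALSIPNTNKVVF and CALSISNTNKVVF.

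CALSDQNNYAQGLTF, a TRAV12-2 and TRAJ26 chain, was found in 4 of 34 control cells with a TRA, 11.8% (3.30 to 27.5), and 4 of 133 ATRA cells, 3.01% (0.825 to 7.52). The 4 control cells were all of the control cells with TRAJ26, so this is not separate from the TRAJ26 ratio above. A TRBV20 chain was beside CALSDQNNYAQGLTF in 2 of the 4 control cells and all 4 ATRA cells, with the CDR3s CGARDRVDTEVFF, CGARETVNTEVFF and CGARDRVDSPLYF. TRBV29 and TRBJ2-1 chains of the kind of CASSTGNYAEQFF and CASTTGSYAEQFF were in 6 control cells and 5 ATRA cells, and TRAV9-2 was beside them in 3 of 3 control and 4 of 4 ATRA cells with a TRA. The 6 control cells had 1 TRB nucleotide sequence and the 3 with a TRA were 1 deposited clonotype, so in control this may be a single clone. The 4 ATRA cells were 2 clonotypes. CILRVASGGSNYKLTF was also found in nonproductive contigs of 3 ATRA cells and 0 control cells. Those contigs had 314 to 352 bases and 11 to 21 UMIs, against medians of 510 bases and 4 UMIs for its productive ATRA contigs. Only 1 of the 3 ATRA cells also carried the TRB group of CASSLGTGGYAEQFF. Nonproductive contigs with the CDR3 of a productive chain in another cell were found in 17 of 160 ATRA and 7 of 74 control cells.

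More ATRA than control cells were in expanded clonotypes, 31.9% against 21.6%. The larger number of ATRA cells may account for this, since drawing them down to 74 gave a mean of 20.6%, within the control interval of 12.9 to 32.7. For division of control clones at a missing TRA, defining clonotypes by TRB alone gave no support. The difference was then larger, 28.6% (18.4 to 40.6) against 45.9% (37.7 to 54.3), at unequal numbers of cells. Drawn down to 70 cells, the ATRA share so defined was 31.97%, within the control interval, so the test decided nothing on such division. An effect of the treatment on expansion was not shown and stays untested with 1 library each.

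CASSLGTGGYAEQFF with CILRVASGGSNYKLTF recurred in both libraries from several nucleotide sequences. Carry-over between the libraries is argued against by 8 of the 9 control cells, whose V segment and nucleotides were absent from ATRA, and errors in reads of 1 clone by 5 of the 9 other encodings, which differed by 2 or more bases or in the V segment from the most frequent one of their library. Among productive chains, chance pairing is argued against by 7 of 9 paired clonotypes with this TRB holding the TRA, 77.8% (40.0 to 97.2). The share without it was 3 of 107, 2.80% (0.582 to 7.98). Shuffling the pairing 10000 times gave 0.775 such clonotypes on average and at most 5. Among clonotypes with 1 TRA and 1 TRB the observed 5 only equalled the highest shuffle. The same shares argue against free RNA of the alpha chain for productive chains only. Nonproductive contigs with its CDR3 were also in ATRA cells without the TRB group. For the 2 pairs identical in nucleotides, carry-over of cells between the libraries cannot be told apart from separate origin. No control cell (0 of 74) had the V, J and nucleotides of a TRB of the 5 largest ATRA clonotypes, but only 2 control cells carried such a pair. In the other direction, 1 of 160 ATRA cells had the TRB of the 2 largest control clonotypes, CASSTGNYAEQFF, identical in V, J and nucleotides, with TRAV9-2 and TRAJ57 rather than TRAJ31 beside it. No biological explanation was tested.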
